A study of Mus musculus with 17 samples.

How the data were processed

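RNA from the skin of C57/BL6j mice, control or given ionizing radiation (IR), was sequenced by the authors as paired-end Smart-Seq2 libraries on an Illumina NovaSeq. The labels give 17 libraries in 7 groups: control at days 0 (2 libraries), 3 (2), 6 (2) and 9 (3) after injury, and irradiated at days 3 (3), 6 (2) and 9 (3). Per the submitters' processing notes, reads were aligned to mm10 (GRCm38) with HISAT2 2.2.1. The tool that counted fragments and its annotation release are not given in the sources used here. The deposited table holds FPKM (fragments scaled by gene length and by the assigned fragments of the library) for 34140 genes in the 17 libraries, of which 19114 are protein coding, with no read counts beside them. The coordinates of 31908 genes equal those of GENCODE release M21.

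The unit was checked by dividing each FPKM by the smallest step the gene's length and the library allow. With gene lengths from GENCODE M21, available for 34067 genes, all values of 31476 genes were whole numbers of fragments within 0.01 fragments. For another 2457 genes a length was found that made all their values whole, so these genes are whole by construction. Of all nonzero values, those of these genes included, 99.904% were whole. The recovered totals gave 25440773 to 30797409 assigned fragments per library (median 29278323). By group they were 25440773 to 29835196 in control day 0, 29379605 to 29650137 in control day 3, 27971207 to 29137652 in control day 6 and 27700147 to 30758592 in control day 9. The irradiated groups had 29278323 to 30797409 at day 3, 27727375 to 28349345 at day 6 and 27404044 to 29604889 at day 9.

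The values as deposited were analysed as log2(FPKM + 1), so fold changes are on that scale and are compressed for genes near or below 1 FPKM. Genes with FPKM of at least 1 in at least 2 libraries were kept (15271 genes). A model with 1 mean per group was fitted to all 17 libraries with limma 3.58.1 (limma-trend, R 4.3.3, with the data.table package, version 1.17.8), and p-values from its moderated tests were adjusted over all tested genes by the method of Benjamini and Hochberg. An adjusted p under 0.05 passed. The comparisons were irradiated against control at days 3, 6 and 9 and averaged with equal weight over these days, an F test of whether the effect of irradiation differed between days, control days 3, 6 and 9 against control day 0, control day 9 against control day 3, and irradiated day 9 against irradiated day 3. The 3 comparisons with day 0 share its 2 libraries, and no irradiated library is labelled day 0. The labels do not state that the libraries of a group come from separate animals, so p measures the spread between these samples. Within groups, Pearson's r of log2(FPKM + 1) across genes (which are not independent replicates) was 0.961 in control day 0, 0.987 in control day 3, 0.967 in control day 6, 0.949 to 0.987 in control day 9, 0.985 to 0.991 in irradiated day 3, 0.945 in irradiated day 6 and 0.977 to 0.99 in irradiated day 9. The labels do not say whether replicate numbers pair control with irradiated libraries, and the main fit did not pair them. Residuals of same-numbered libraries of a day correlated across genes with r from -0.122 to 0.298. With 2 or 3 libraries per group these values cannot show whether the libraries were paired.

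In addition, 36 gene lists written from general knowledge were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. For each list, members passing over all genes and adjusted over the list alone were counted. The alternatives were camera with an estimated correlation and fry. The genes named were set by a rule: for each irradiation comparison, the 8 highest and 8 lowest log2 fold changes among named protein-coding genes that passed, had a mean FPKM of at least 5 in the higher group and had every irradiated library on the same side of every control library of that day; for lists with camera adjusted p under 0.05 or at least 3 passing members, up to 4 passing members with the largest change and mean FPKM of at least 1; always Tgfb1, Tgfb2, Tgfb3, Tgfbr1, Tgfbr2, Smad2, Smad3, Smad4, Smad7, Cdkn1a, Ccng1, Eda2r, Phlda3 and Mdm2; the 5 highest and 5 lowest for comparisons between days; and up to 6 genes for the F test. The comparisons, lists, rule and alternatives named next were fixed before the data were examined. Some genes that the rule names are not reported here. Genes given outside this rule are said to be chosen after their values were seen.

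The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a minimum FPKM of 5, median-of-ratios scaling of FPKM, quantile normalization, a fit of only the groups compared, a replicate block, array quality weights, a robust fit, an added threshold of 1 on the absolute log2 fold change, and each replicate left out in turn. Chosen after seeing the data were limma-voom on the recovered whole fragments, FPKM rescaled to the nuclear genes, the average without day 6, and gene ontology terms (hypergeometric test, adjusted by the method of Benjamini and Hochberg, terms of 10 to 300 genes in a background of 12365 annotated tested genes, 1848 terms). Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 prepared the tables. The fit was tested on simulated data with 200 changed genes: changes of 1 and 2 on the log2 scale were recovered at 92% and 96% averaged over days, 76% and 88% at day 3, 73% and 85% at day 6, and 83% and 90% at day 9, with 4.82% to 7.49% false among the genes called. The simulation drew independent normal noise for each gene, with the same spread in every library. It changed only genes with a mean log2(FPKM + 1) of at least 2, by the same amount on every day. Its rates need not hold for the real libraries, where leaving out 1 library could move the counts strongly. Splicing and sequence variants were not analysed here, since the table holds gene totals.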

Results

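Skin of C57/BL6j mice was sampled at 0, 3, 6 and 9 days after injury without radiation, and at 3, 6 and 9 days with ionizing radiation (IR). The series asks which molecules take part in wound healing after IR, and its title names TGF-β1 and the TGFβ-SMAD pathway. The 17 libraries held 25440773 to 30797409 assigned fragments each, with 2 or 3 libraries per group. Mitochondrially encoded genes took 21.7% and 31.8% of summed FPKM in the 2 day-0 libraries and 8.33% to 12.6% in the other libraries. Changes below are log2 fold changes of FPKM + 1 with their standard error (SE), group means are FPKM with their standard deviation, and coordinates are GRCm38/mm10. In the comparison averaged over days, FPKM means and deviations pool all libraries of an arm from days 3, 6 and 9. Those deviations thus include differences between days, whereas the log2 fold change weights the days equally.

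In irradiated skin, interferon-induced genes, p53 target genes and some chemokine genes rose, and globin and class II antigen presentation genes fell. This was irradiated against control, averaged over days 3, 6 and 9, with 8 libraries against 7. Here and in the other comparisons of irradiated with control skin, rose and fell mean higher and lower than in control skin of the same days. Ifit1 (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009), which binds foreign RNA, rose by 2.94 (SE 0.34, adjusted p 0.000559), from 6.70 ± 2.4 FPKM to 84.7 ± 62.6. The transcription factor gene Irf7 (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481), which amplifies the interferon response, rose by 2.88 (SE 0.349, adjusted p 0.000687), from 10.2 ± 4.41 to 94.7 ± 46.5 FPKM. All 25 genes of the interferon response list rose, with a median of 2.2, and 25 did when adjusted over the list alone. The camera adjusted p was 1.61e-33 (adjusted p = 0.113 with an estimated correlation). Of 26 p53 target genes, 17 rose and none fell (18 adjusted over the list alone, median 0.48, camera adjusted p 6.62e-16, and 0.0011 with an estimated correlation). Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090979 to 29100722), whose product stops the cell cycle, rose by 1.04 (SE 0.122, adjusted p 0.00059), from 80.5 ± 22.1 to 170.1 ± 33.6 FPKM. Ccng1 (ENSMUSG00000020326, chromosome 11, 40748552 to 40755311) rose by 0.80, Phlda3 (ENSMUSG00000041801, chromosome 1, 135766119 to 135769136) by 0.59 and Mdm2 (ENSMUSG00000020184, chromosome 10, 117688875 to 117710758) by 0.54, while the receptor gene Eda2r stood at 0.50 with an adjusted p of 0.115.

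Among 32 inflammatory cytokines and chemokines, 8 rose and none fell averaged over the days (10 adjusted over the list alone, median 0.64, adjusted p 2.35e-06, and 0.665 with an estimated correlation). Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453), which draws monocytes, rose by 2.57, from 19.7 ± 14.3 to 120.6 ± 74.1 FPKM, and Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), which draws T cells, rose by 2.60. Of 25 macrophage and monocyte markers, 7 rose and 1 fell (10 and 2 adjusted over the list alone, adjusted p 0.000123, and 0.665 with an estimated correlation). The Fc receptor gene Fcgr1 rose by 1.61 and the scavenger receptor gene Cd163 by 1.57, and Ccr2, the receptor for Ccl2, fell by 1.55. The acute-phase gene Serpina3n (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329) rose by 2.67, from 63.7 ± 57.6 to 366.3 ± 297 FPKM. Class II genes are expressed by cells that show antigen to T cells. H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287827) fell by 2.28 (SE 0.217, adjusted p 0.000173), from 224.1 ± 94.5 to 44.7 ± 14 FPKM, with H2-Eb1 (-2.12), H2-Ab1 (-1.95) and the invariant chain gene Cd74 (-1.90). These 4 genes belong to a list of 12 Langerhans and dendritic cell markers, of which 6 fell and none rose (8 adjusted over the list alone, adjusted p 8.03e-11, and 0.113 with an estimated correlation). The other members that fell were Flt3 and Ccr7, named after their values were seen. All 5 red blood cell markers fell (5 adjusted over the list alone, median -2.28, adjusted p 9.76e-11, and 0.0668 with an estimated correlation). The beta-globin gene Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096) fell by 3.997 (SE 0.286, adjusted p 1.66e-05) and the alpha-globin gene Hba-a1 (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465) by 3.39. Reads of such near-identical copies, and of Ifit3 and Ifit3b, are hard to assign to 1 gene. In all, 666 genes rose and 392 fell, of which 189 and 28 by at least 1 on the log2 scale. The excess of risen genes was absent under quantile normalization (712 rose and 715 fell) and nearly so without control_day6 replicate 1 (520 and 502). Single libraries moved the count: 571 genes passed without control_day3 replicate 1, 598 without control_day3 replicate 3 and 1697 without irradiated_day6 replicate 3. The call of Ccr2 ended without control_day3 replicate 1 (adjusted p 0.0517) and that of Cd163 with no filter on low values and without any of 9 libraries (adjusted p 0.0542 to 0.0797).

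**Figure D1:**
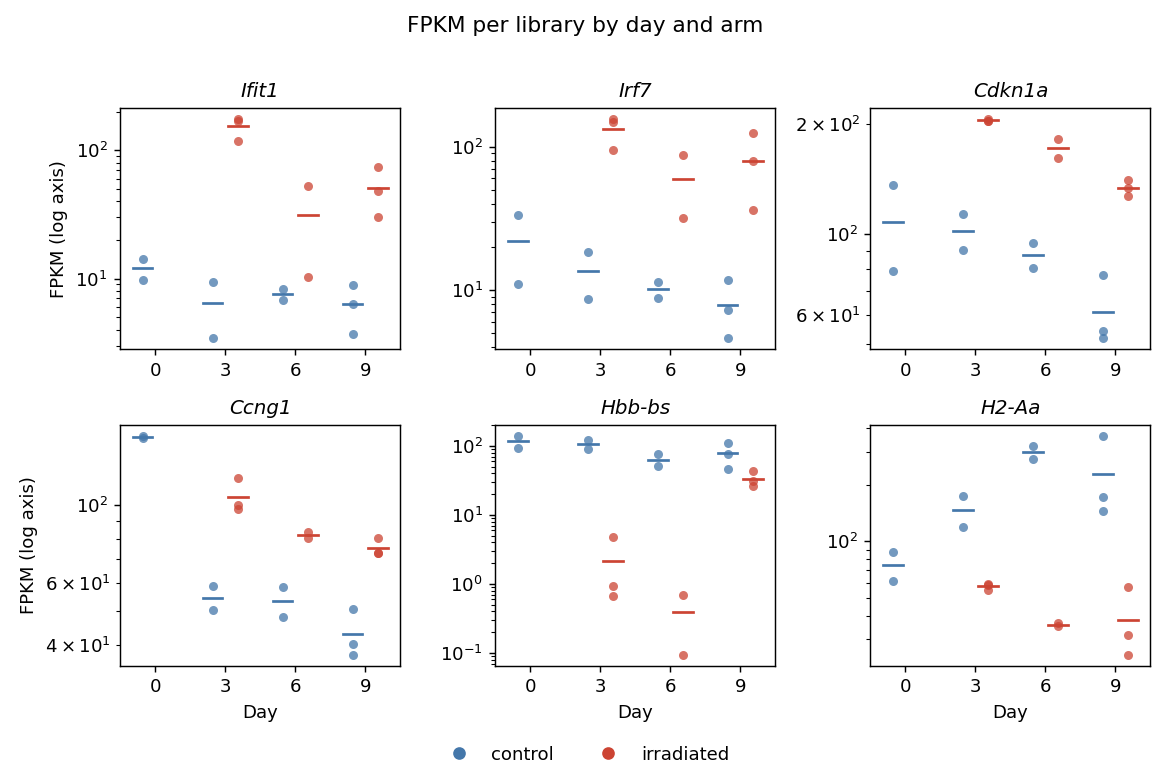
FPKM (log axis) against day after injury for Ifit1, Irf7, Cdkn1a, Ccng1, Hbb-bs and H2-Aa, with 1 point per library, a line at each group mean, control in blue and irradiated in red. Ifit1 averaged 154.1 FPKM in irradiated skin at day 3 against 6.42 in control, and Hbb-bs 2.12 against 105.2.

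The transforming growth factor gene of the title, Tgfb1 (ENSMUSG00000002603, chromosome 7, 25687002 to 25705077), averaged 19.2 ± 4.19 FPKM in irradiated and 17.6 ± 3.1 in control skin, a log2 fold change of 0.15 (SE 0.17, adjusted p 0.652). By day its values were 0.10 at day 3, 0.45 at day 6 and -0.09 at day 9, none passing. Tgfb2 (ENSMUSG00000039239, chromosome 1, 186622792 to 186705989) fell averaged over days by 0.49 (SE 0.102, adjusted p 0.0128) and at day 9 by 0.90 (SE 0.159, adjusted p 0.0111), from 7.71 ± 1.09 to 3.69 ± 0.787 FPKM. The day-9 call ended without irradiated_day9 replicate 3 (adjusted p 0.0582). In control skin Tgfb2 had risen between days 3 and 9, as given below. Averaged over days, Tgfb3 stood at -0.47 (adjusted p 0.114), the receptor genes Tgfbr1 at -0.16 and Tgfbr2 at 0.34, and the signal transducer genes Smad2 at 0.00, Smad3 at -0.08, Smad4 at 0.02 and Smad7 at 0.12, none passing. Averaged over days, 1 of the 27 TGF-beta ligands, receptors and SMADs rose and 1 fell (the same numbers adjusted over the list alone, adjusted p 0.735). None of 20 TGF-beta target genes passed, over all genes or adjusted over the list alone (limma, camera adjusted p 0.328). At day 9 the target genes had a median of -0.73 (camera adjusted p 0.000221, and 0.544 with an estimated correlation), with 1 of 20 falling, Cdh2 (-0.86), and 5 adjusted over the list alone. Cdh2 ended without any day-9 library except control_day9 replicate 3 (adjusted p 0.0591 to 0.175), with pseudocount 0.1 (0.0857) and with no filter on low values (0.0885).

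**Figure D2:**
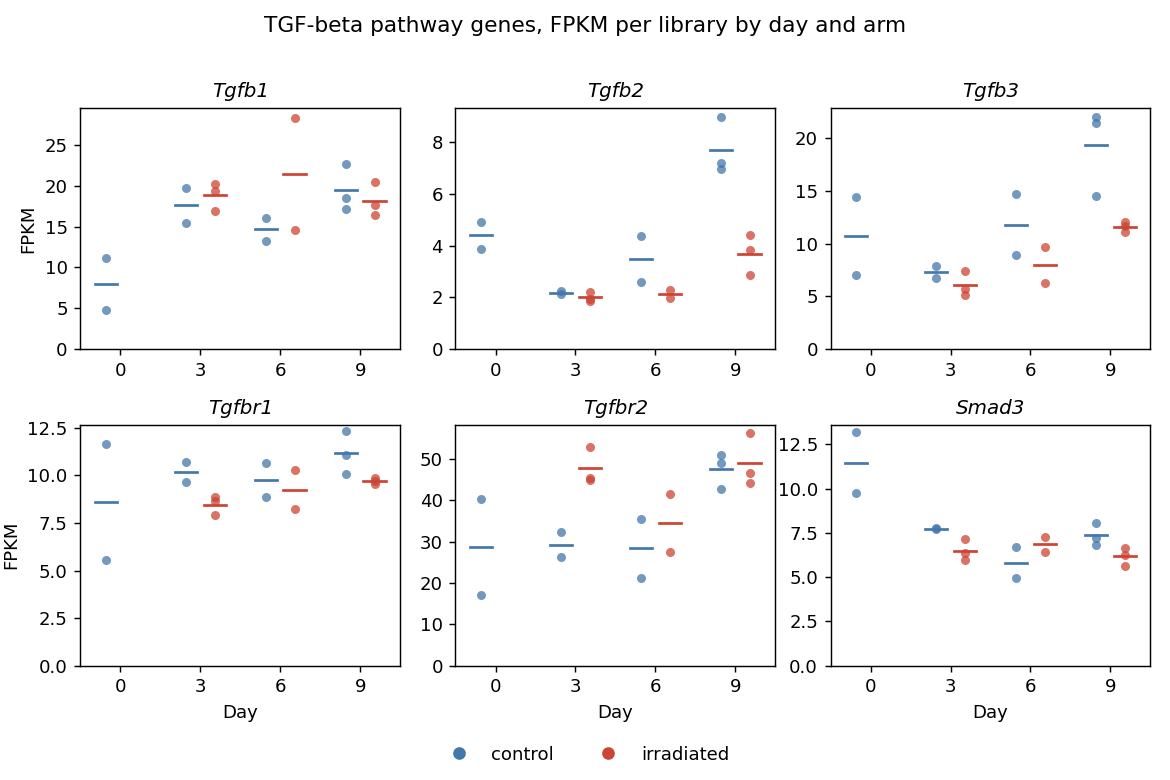
FPKM (linear axis from 0) against day after injury for Tgfb1, Tgfb2, Tgfb3, Tgfbr1, Tgfbr2 and Smad3, with 1 point per library, a horizontal line at each group mean, control in blue and irradiated in red. Tgfb2 at day 9 averaged 7.71 FPKM in control and 3.69 in irradiated skin, and Tgfb1 in control skin averaged 7.94 FPKM at day 0 and 17.6 at day 3.

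At day 3, interferon-induced and p53 target genes rose and the globins fell in irradiated skin (irradiated against control, day 3; 3 libraries against 2). Ifit1 rose by 4.49 (SE 0.588, adjusted p 0.00279), from 6.42 ± 4.21 to 154.1 ± 31.6 FPKM. Ifit3 rose by 4.41, Rsad2, which blocks viral replication, by 4.38 and Cxcl10 by 4.14. In the interferon list 23 of 25 genes rose and none fell (25 adjusted over the list alone, median 2.96, camera adjusted p 4.39e-48, and 0.0462 with an estimated correlation). Of the p53 targets 10 of 26 rose (18 adjusted over the list alone, median 0.60, adjusted p 3.7e-20, and 0.000386 with an estimated correlation), among them the death effector gene Bax by 0.94, Trp53inp1 by 1.48, Ccng1 by 0.95 and Cdkn1a by 1.01 (SE 0.211, adjusted p 0.0296). Mdm2 (0.69, adjusted p 0.0731) and Phlda3 (0.35) did not pass. Of 30 cell cycle genes, 2 fell and none rose, and 21 fell when adjusted over the list alone (median -0.47, adjusted p 3.21e-16, and 0.632 with an estimated correlation). The 2 that fell over all genes were the spindle gene Nusap1, by 0.71, and Tyms. The call of Tyms ended with pseudocount 0.1 (limma adjusted p 0.0657), with no filter on low values (0.0534) and with a replicate block (0.071). The centromere histone gene Cenpa, which is not on the list, fell by 0.72. Hbb-bs fell by 5.31 (SE 0.495, adjusted p 0.000891), from 105.2 ± 23.3 to 2.12 ± 2.29 FPKM, with all 5 red blood cell markers (5 adjusted over the list alone, camera adjusted p 4.46e-14, and 0.0266 with an estimated correlation). In total 238 genes rose and 44 fell. With array quality weights 644 rose and 598 fell, so the excess of risen genes was small under that setting. The count was 129 genes without control_day3 replicate 1, 26 without control_day3 replicate 3, 140 without irradiated_day3 replicate 1 and 147 without irradiated_day3 replicate 2. Without control_day3 replicate 3 the calls of Ifit1 (adjusted p 0.076), Ifit3 (0.108), Rsad2 (0.121), Cxcl10 (0.188), Bax (0.235), Trp53inp1 and Cenpa ended, without control_day3 replicate 1 those of Ccng1 (0.0593), Trp53inp1, Cxcl10 and Cenpa, and without any of the 5 day-3 libraries that of Cdkn1a (0.0772 to 0.408). With no filter on low values and with a replicate block the calls of Cdkn1a (0.0614 and 0.0792) and Nusap1 (0.0549 and 0.0559) ended, that of Nusap1 also without any day-3 library but irradiated_day3 replicate 1 (0.0855 to 0.303). Bax ended without irradiated_day3 replicate 2 as well (0.0512) and Cxcl10 without irradiated_day3 replicate 1 (0.052), whereas Hbb-bs and Hba-a1 passed under every alternative run.

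By day 6, class II and globin genes were lower and some p53 targets higher in irradiated skin (irradiated against control, day 6; 2 libraries against 2). H2-Aa fell by 3.01 (SE 0.411, adjusted p 0.0125), from 297.3 ± 31.7 to 35.9 ± 0.779 FPKM, and Hbb-bs by 5.54 (SE 0.542, adjusted p 0.00177), from 63.4 ± 17.6 to 0.391 ± 0.421. Of the Langerhans and dendritic cell markers 5 of 12 fell, the 4 class II genes and Flt3 (9 adjusted over the list alone, median -1.11, adjusted p 1.41e-11, and 0.112 with an estimated correlation). Among the p53 targets 3 of 26 rose (13 adjusted over the list alone, adjusted p 2.07e-07, and 0.0295 with an estimated correlation). These were the exonuclease gene Aen by 0.80, Phlda3 by 0.79 and the death receptor gene Tnfrsf10b by 0.73. Cdkn1a stood at 0.96 (adjusted p 0.116) and Ccng1 at 0.62. Ch25h, which makes an antiviral oxysterol, rose by 2.51. No interferon list gene passed (limma; 3 adjusted over the list alone, median 1.29, camera adjusted p 2.79e-10, and 0.554 with an estimated correlation), and no differentiated keratinocyte gene (1 of 27 lower adjusted over the list alone, median -0.90, adjusted p 1.34e-07, and 0.442 with an estimated correlation). In the limma fit of all 17 libraries 42 genes passed, 23 up and 19 down (2345 had an unadjusted p under 0.05), against 0 with array quality weights or with only these 4 libraries. Under limma-voom the calls of the globins (Hbb-bs 0.0646), H2-Ab1 (0.0524), Cd74 (0.0514), Tnfrsf10b (0.0524) and Ch25h (0.108) ended, and with a replicate block those of all 4 class II genes (0.0502 to 0.149), Phlda3 (0.0502), Tnfrsf10b and Ch25h. With no filter on low values H2-Ab1 (0.0622) and Cd74 (0.0548) ended, H2-Ab1 also with pseudocount 0.1 (0.0509) or robust eBayes (0.0512), Ch25h with pseudocount 5 (0.0699) and Tnfrsf10b with nuclear-total scaling (0.0581). The count was 7 without control_day6 replicate 1, 7 without irradiated_day6 replicate 1 and 985 without irradiated_day6 replicate 3, and without control_day6 replicate 1 or irradiated_day6 replicate 1 the calls of H2-Aa (adjusted p 0.0932 and 0.102), the other 3 class II genes, Aen, Phlda3, Tnfrsf10b and Ch25h ended. Without control_day6 replicate 2 those of H2-Ab1 (0.105), Cd74 (0.109), H2-Eb1 (0.0675), Phlda3 (0.0511), Tnfrsf10b (0.073) and Ch25h (0.118) ended.

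At day 9, most interferon genes and some mast cell, adipocyte and hypoxia genes were higher in irradiated than in control skin. Class II genes were lower (irradiated against control, day 9, 3 libraries against 3). In control skin, adipocyte markers had themselves fallen since day 0, and hypoxia and glycolysis genes since day 3, as given below. Irradiated skin was not compared with day 0. The mast cell protease genes Cma1 (ENSMUSG00000022225, chromosome 14, 55941453 to 55944661) and Mcpt4 rose by 2.80 (SE 0.421, adjusted p 0.00642) and 2.42, Cma1 from 7.23 ± 0.421 to 58.9 ± 20.7 FPKM. In the mast cell list 6 of 10 genes rose (8 adjusted over the list alone, median 1.44, adjusted p 1.83e-06, and 0.515 with an estimated correlation). Adipocyte markers rose in 6 of 20 genes (9 adjusted over the list alone, median 1.02, adjusted p 4.88e-08, and 0.544 with an estimated correlation), with the hormone gene Adipoq (ENSMUSG00000022878, chromosome 16, 23146536 to 23158028) up by 2.53 and the complement protease gene Cfd by 2.31. Of 20 hypoxia and glycolysis genes 9 rose (15 adjusted over the list alone, median 0.61, adjusted p 1.85e-09, and 0.355 with an estimated correlation), including the glucose carrier gene Slc2a1 (1.12) and the oxygen sensor gene Egln3 (1.08). Serpina3n rose by 3.86, from 11.98 ± 5.84 to 177.1 ± 33.4 FPKM, and the alarmin gene Il33 by 1.72. Interferon genes rose in 19 of 25 cases (25 adjusted over the list alone, median 2.07, adjusted p 6.42e-19, and 0.375 with an estimated correlation) and p53 targets in 6 of 26 (14 adjusted over the list alone, median 0.41, adjusted p 2.33e-08, and 0.0166 with an estimated correlation), with Cdkn1a up by 1.14 and Phlda3 by 0.63.

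None of the 5 red blood cell markers passed at day 9 (limma, 3 lower adjusted over the list alone), with Hbb-bs at -1.15 (adjusted p 0.145). The genes that fell at day 9 included H2-Aa, by 2.52 (SE 0.336, adjusted p 0.00415), and Ptn, a growth factor gene, by 2.39, from 121.6 ± 36.2 to 21.8 ± 2.17 FPKM. Langerhans and dendritic cell markers fell in 6 of 12 genes, the 4 class II genes, Flt3 and Ccr7 (8 adjusted over the list alone, median -0.85, adjusted p 3.94e-08, and 0.355 with an estimated correlation). Hair follicle genes and hair keratins fell in 3 of 28 (11 adjusted over the list alone, median -1.11, adjusted p 4.33e-06, and 0.619 with an estimated correlation), Krt72 of the inner root sheath by 2.39. Fibrillar collagens and matrix structure genes had a median of -0.86 with none of 24 passing over all genes or adjusted over the list alone (limma, camera adjusted p 7e-07, and 0.581 with an estimated correlation). In control skin the hair and collagen lists had risen between days 3 and 9, as given below. In the comparison 356 genes rose and 466 fell, 149 and 117 of them by at least 1 on the log2 scale. The share higher was 43.3%, against 28.8% with FPKM rescaled to the nuclear genes, 35.2% after median-of-ratios scaling, 52.7% at a minimum FPKM of 5 and 56.2% with array quality weights, so which direction held more genes depended on the setting. Of irradiated against control, day 9, the count fell to 225 without control_day9 replicate 1, 100 without control_day9 replicate 2, 348 without irradiated_day9 replicate 2 and 94 without irradiated_day9 replicate 3. The calls of Cma1, Mcpt4, Serpina3n, Ptn, H2-Aa, Phlda3 and Ccng1 held under every alternative run, whereas those of Adipoq (adjusted p 0.0882 and 0.0889), Cfd, Slc2a1, Egln3 and Il33 ended without control_day9 replicate 2 or irradiated_day9 replicate 3, that of Cdkn1a without control_day9 replicate 2 (0.0532), and that of Krt72 without any irradiated library of day 9 (0.0553 to 0.119), with no filter on low values (0.0567) and with only these groups fitted (0.113). With only these groups fitted Il33 (0.0636) and Cd74 (0.0509) ended too, and with no filter Egln3 (0.0505). Without single other day-9 libraries Egln3 (0.0622 to 0.097), Il33 (0.0519 and 0.0582) and Adipoq (0.0539) ended as well, and Cd74 without irradiated_day9 replicate 3 (0.0505). Under limma-voom the calls of Krt72 (0.0858), Krt31 (0.099) and Krt83 (0.0632), the 3 hair list genes that passed, ended.

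**Figure D3:**
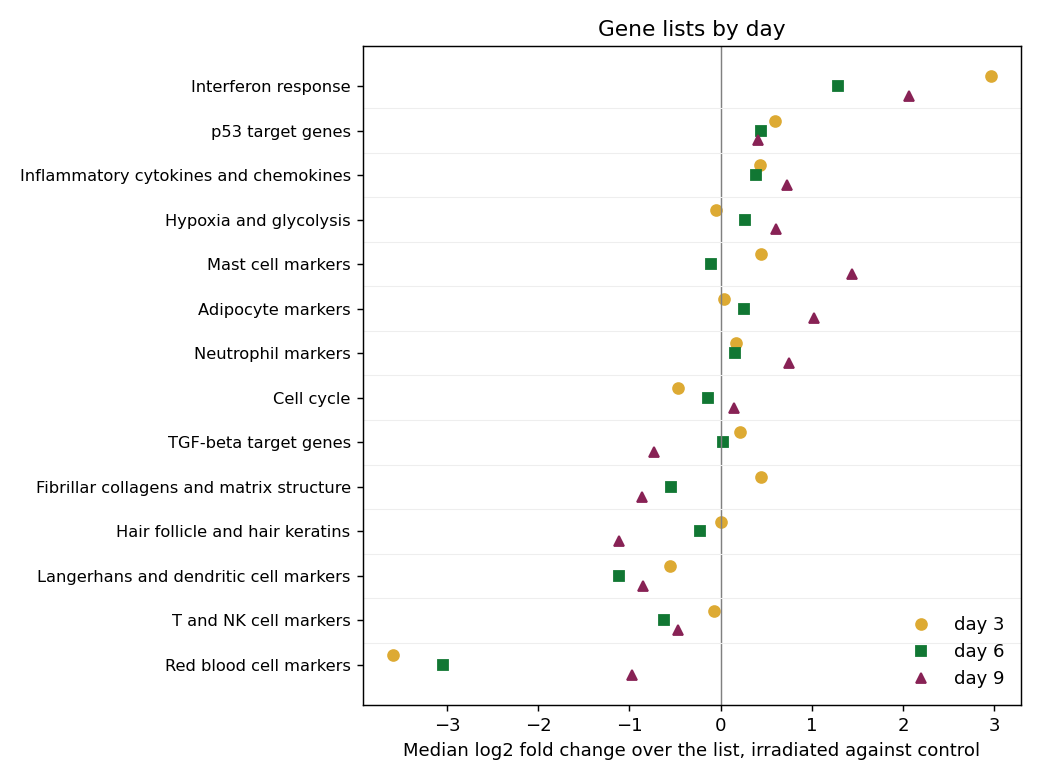
Median log2 fold change of FPKM + 1, irradiated against control, on the horizontal axis for 14 gene lists, with 1 point each for days 3 (circles), 6 (squares) and 9 (triangles). The interferon response list lies at 2.96, 1.29 and 2.07, the p53 target list at 0.60, 0.44 and 0.41, and the red blood cell list at -3.59, -3.04 and -0.98.

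The effect of irradiation was tested for a difference between days with an F test, which 2 genes passed (2337 had an unadjusted p under 0.05). Igfbp3 (ENSMUSG00000020427, chromosome 11, 7206086 to 7213923), whose product binds insulin-like growth factors, had effects of 0.18, 0.41 and -0.78 at days 3, 6 and 9 (SE 0.108, 0.118 and 0.0962), and the effect at day 9 alone passed (adjusted p 0.00415). Tmprss11e (ENSMUSG00000054537, chromosome 5, 86705186 to 86745815), a serine protease gene of squamous epithelium, had effects of -0.15, -1.08 and 0.97 (SE 0.169, 0.185 and 0.151), passing at day 6 (adjusted p 0.0362) and day 9 (0.00696). Each call ended under 5 of the settings, and with single libraries left out the adjusted p reached 0.258 for both genes. The difference of the irradiation effect between days gave 7 genes without control_day6 replicate 2, 74 without control_day9 replicate 3 and 351 without irradiated_day6 replicate 3. It gave 0 (limma) without control_day3 replicate 1 or 3, control_day6 replicate 1, control_day9 replicate 1 or 2, irradiated_day3 replicate 1, irradiated_day6 replicate 1, or irradiated_day9 replicate 2 or 3. Without irradiated_day9 replicate 1 it gave 2 genes, neither of them Igfbp3 (adjusted p 0.0562) or Tmprss11e (0.0575), and without irradiated_day3 replicate 2 it gave 3 genes, Igfbp3 (0.0689) not among them.

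Without irradiation, injured skin at day 3 had gained wound keratins and proliferation genes and lost muscle transcripts (control day 3 against control day 0; 2 libraries against 2). The wound keratin gene Krt6b (ENSMUSG00000023041, chromosome 15, 101676034 to 101680289) rose by 7.15 (SE 0.592, adjusted p 2.74e-05), from 24.97 ± 16.1 to 3322 ± 435 FPKM, with Krt16 (6.02) and the acute-phase gene Saa3 (6.65). All 30 cell cycle genes rose (median 1.61, adjusted p 2.1e-16, and 0.809 with an estimated correlation), among them Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361) by 1.96. Of 23 skeletal muscle markers 20 fell (median -2.45, adjusted p 1.25e-14, and 0.809 with an estimated correlation), with the calcium buffer gene Pvalb lower by 3.83 on the log2 scale. Tgfb1 rose by 1.15 (SE 0.323, adjusted p 0.0148), from 7.94 ± 4.48 to 17.6 ± 3 FPKM, and Smad3 fell by 0.50. The call of Tgfb1 ended without control_day0 replicate 1 (0.61, adjusted p 0.166), without control_day3 replicate 1 (0.106) and with only these groups fitted (0.108). In total 3937 genes rose and 1887 fell, or 3425 in all without control_day3 replicate 1 and 2487 with only these groups fitted. Median-of-ratios scaling, which moved the median of all genes by -0.17, cut the share that rose from 67.6% to 43.0%.

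At day 6, cornified envelope and class II genes had risen (control day 6 against control day 0; 2 libraries against 2). Krt6b rose by 7.15 and the cornified envelope gene Rptn by 7.87, from 1.20 ± 0.34 to 509.9 ± 19.4 FPKM, with 15 of 27 differentiated keratinocyte genes rising and none falling (median 2.64, adjusted p 0.000141, and 0.879 with an estimated correlation). H2-Aa rose by 2.003 (SE 0.411, adjusted p 0.00282), and 8 of 12 Langerhans and dendritic cell markers rose, 4 of them class II genes (adjusted p 0.0149, and 0.879 with an estimated correlation). With array quality weights the calls of H2-Aa (adjusted p 0.0502), H2-Eb1 (0.0612) and H2-Ab1 (0.0663) ended. Tgfb1 rose by 0.90 (adjusted p 0.0469), a call that ended without control_day0 replicate 1 (0.37, adjusted p 0.416), without either control day-6 library (0.0874 and 0.179) and under 8 of the other settings (0.0632 to 0.202), median-of-ratios scaling and limma-voom among them. In total 3221 genes rose and 2173 fell, 773 in all with only these groups fitted and 2683 with array quality weights, and the share that rose went from 59.7% to 43.9% under median-of-ratios scaling, which moved the median by -0.10.

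By day 9, collagen and hair genes had risen and adipocyte and nerve genes had fallen (control day 9 against control day 0; 3 libraries against 2). Of the collagens and matrix structure genes 22 of 24 rose (median 2.48, adjusted p 2.38e-06, and 0.881 with an estimated correlation), Col12a1 by 5.05 and the matrix gene Postn by 3.64, from 72.2 ± 44.6 to 831.4 ± 128 FPKM. Of 28 hair follicle genes and hair keratins 22 rose and 1 fell (23 and 1 adjusted over the list alone, median 1.59, adjusted p 0.00268, and 0.881 with an estimated correlation), Krt71 by 6.42. Genes on the myofibroblast contractile list moved both ways, with 4 of 12 rising and 6 falling (5 and 6 adjusted over the list alone). The smooth muscle actin gene Acta2 rose by 2.16 and the desmin gene Des fell by 3.61. Des is also on the list of pericyte and vascular smooth muscle markers, and the muscle actin gene Acta1 fell by a like amount (3.77). Which cells lost Des was not tested. TGF-beta target genes rose in 15 of 20 (median 1.65, adjusted p 0.000251, and 0.841 with an estimated correlation), and Tgfb1 (1.28), Tgfb2 (0.69), Tgfb3 (0.85) and Tgfbr2 (0.83) rose while Smad3 fell by 0.57. Without control_day0 replicate 1 the calls of Tgfb1 (0.75, adjusted p 0.0652) and Tgfb3 (0.37, adjusted p 0.362) ended, the latter also without control_day9 replicate 1 (0.0778) or 2 (0.0788), with no filter on low values (0.0569) and with only these groups fitted (0.11). Adipocyte markers fell in 14 of 20 (median -1.48, adjusted p 8.89e-07, and 0.841 with an estimated correlation), and of 11 Schwann cell and nerve markers 7 fell and 1 rose (adjusted p 0.00219, and 0.841 with an estimated correlation). The muscle actin gene Acta1 fell by 3.77, from 9318 ± 1040 to 706.4 ± 231 FPKM. In total 4644 genes rose and 2754 fell, with 62.8% higher as deposited and 50.1% after median-of-ratios scaling, which moved the median by -0.11.

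Between days 3 and 9, unirradiated skin gained matrix and hair genes and lost sebaceous lipid genes (control day 9 against control day 3; 3 libraries against 2). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) rose by 2.88 (SE 0.561, adjusted p 0.00594), from 492.5 ± 249 to 3419 ± 457 FPKM, with 18 of 24 list members (21 adjusted over the list alone, median 2.08, adjusted p 1.86e-15, and 0.578 with an estimated correlation). The hair sheath keratin gene Krt71 (ENSMUSG00000051879, chromosome 15, 101733950 to 101743109) rose by 6.83, with 16 of 28 hair list genes rising and 1 falling (23 and 1 adjusted over the list alone, median 1.70, adjusted p 1.86e-10, and 0.578 with an estimated correlation). The protease-like gene Prss35 rose by 6.98, Tgfb2 by 1.45 and Tgfb3 by 1.27, whereas Tgfb1 stood at 0.14 (adjusted p 0.782). Of 20 sebaceous gland and lipid genes 17 fell (1 rose and 19 fell adjusted over the list alone, median -1.83, adjusted p 3.67e-09, and 0.578 with an estimated correlation), the fatty acid elongase gene Elovl3 by 3.28. In the hypoxia and glycolysis list 11 of 20 fell (13 adjusted over the list alone, adjusted p 1.81e-05, and 0.578 with an estimated correlation). Here 1224 genes rose and 1556 fell (44.0% higher, but 60.1% under median-of-ratios scaling). The count was 1267 without control_day3 replicate 1, 299 without control_day3 replicate 3, 1766 without control_day9 replicate 1 and 1347 without control_day9 replicate 2. The call of Tgfb3 ended without control_day3 replicate 1 or 3, and that of Col1a1 without control_day3 replicate 3 (log2 fold change 2.34). Under limma-voom the calls of Krt71 (adjusted p 0.0522), Krt25 (0.101), Krt27 (0.0735) and Krt73 (0.191) ended.

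In the irradiated arm, globin genes rose between the same days (irradiated day 9 against irradiated day 3; 3 libraries against 3). Hbb-bs rose by 3.66 (SE 0.442, adjusted p 0.00499), from 2.12 ± 2.29 to 33.3 ± 8.85 FPKM, the kallikrein protease gene Klk14 by 3.68 and Rptn by 2.83, and 3 of 5 red blood cell markers rose (5 adjusted over the list alone, adjusted p 4.13e-09, and 0.092 with an estimated correlation). Of the interferon genes 1 of 25 fell, Mx2 by 1.52 (10 adjusted over the list alone, median -0.91, adjusted p 4.82e-09, and 0.853 with an estimated correlation). No collagen list gene passed (limma; 5 adjusted over the list alone, median 0.87, camera adjusted p 1.5e-07, and 0.853 with an estimated correlation), and Tgfb2 stood at 0.63 (adjusted p 0.0772). A total of 58 genes rose and 89 fell (2472 had an unadjusted p under 0.05). With pseudocount 0.1, 69 rose and 59 fell, and without irradiated_day9 replicate 3, 38 and 28. With pseudocount 5, 73 rose and 190 fell, so which direction held more genes depended on the setting. The count was 13, 23 and 31 without irradiated_day3 replicates 1, 2 and 3, and 98, 15 and 66 without irradiated_day9 replicates 1, 2 and 3. The call of Mx2 ended without any of these but irradiated_day9 replicate 1 (adjusted p 0.0536 to 0.159), with pseudocount 0.1 (0.0903), with no filter on low values (0.0677) and with a replicate block (0.0528), and that of Rptn without irradiated_day3 replicate 2 or 3 or irradiated_day9 replicate 2 (0.0515 to 0.0746).

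**Figure D4:**
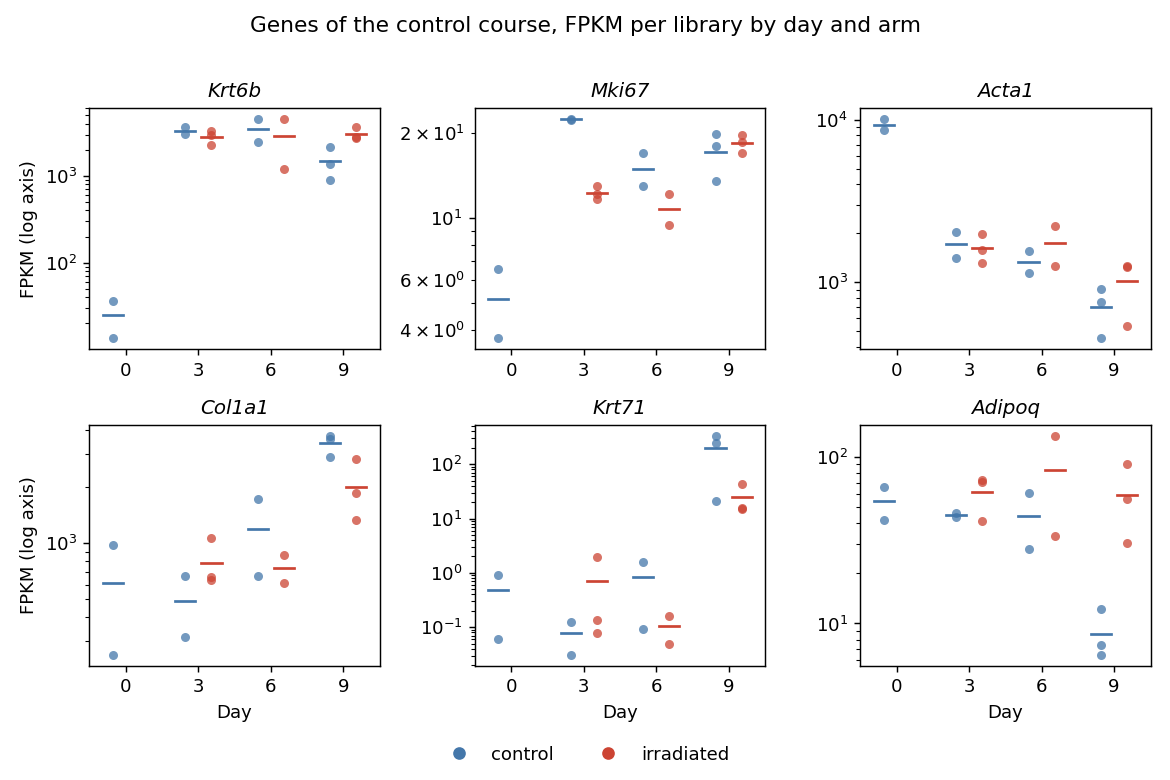
FPKM (log axis) against day after injury for Krt6b, Mki67, Acta1, Col1a1, Krt71 and Adipoq, with 1 point per library, a line at each group mean, control in blue and irradiated in red. Krt6b in control skin goes from 24.97 FPKM at day 0 to 3322 at day 3, and Col1a1 from 492.5 at day 3 to 3419 at day 9.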

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

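Chosen only after the result was seen were the tests of less blood and of near-identical globin copies, and the use of the rotation test fry to single out the red blood cell list.

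The effect of irradiation on Igfbp3 differed between days (F test adjusted p 0.0437), at 0.18, 0.41 and -0.78 on days 3, 6 and 9, and no cause was tested. For Tmprss11e the effect also differed between days (F test adjusted p 0.0437), with -1.08 at day 6 and 0.97 at day 9, and again no cause was tested. Each of these calls lay near the threshold and ended under some settings and with single libraries left out, as given above.

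The red blood cell markers fell at day 3 in irradiated skin, and none passed at day 9 (limma, 3 of 5 lower adjusted over the list alone). The effect at day 9 minus that at day 3 had a median of 3.36 over 5 genes (fry adjusted p 0.0071; camera adjusted p 9.39e-08, and 0.361 with an estimated correlation). Less blood in the irradiated day-3 samples is argued against by 8 platelet genes, whose summed fragments, relative to the library total, were 1.57 to 6.04 times the control mean, although Ppbp carried most of the sum (2.01 at day 3, not passing, adjusted p 0.432), Gp1bb and Itga2b stood near 0 (-0.08 each), and platelets held in a clot are not told from those in vessels. Reads moving between near-identical copies are argued against by the summed fragments of the 4 globin genes, at most 0.0447 of the control mean (52, 183 and 38 fragments against 3506 and 4755), while at day 9 the sums were 0.369 to 0.569 of the control mean, overlapping the control libraries at 0.55 to 1.41. The radiation itself stays open as a biological explanation and was not tested, since the labels give no irradiated field and no blood sample.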

How the results depend on the processing

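The alternatives chosen only after the data were seen were limma-voom, FPKM rescaled to the nuclear genes and the average without day 6. Of 10393 values for named genes under all alternatives, 9039 kept their side of the threshold, 1337 lost the call, 17 gained one and no called gene turned direction. For the lists, 2816 of 3132 values stayed, 229 lost and 81 gained the call, and 6 turned direction, all at day 6 with 1 library left out. Their adjusted p over the left-out libraries, with the turn named, ran from 5.68e-07 to 0.476 (without irradiated_day6 replicate 1) for matrix remodelling, 8.5e-06 to 0.848 (irradiated_day6 replicate 1) for inflammatory genes, 0.000102 to 0.989 (control_day6 replicate 1) for cell cycle and 5.39e-07 to 0.895 (control_day6 replicate 2) for hypoxia. Wound keratinocytes ran from 0.00119 to 0.936 (turned at 0.00309 without control_day6 replicate 1) and mast cells from 1.44e-05 to 0.737 (turned at 0.0281 without irradiated_day6 replicate 3). Of 144 irradiation list tests 70 passed, 21 under fry and 6 with an estimated correlation.

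Counts of passing genes that moved by over 1.5 times follow. An absolute log2 fold change of at least 1, which removes genes by construction, left 217 averaged over days, 163 at day 3, 24 at day 6, 266 at day 9, 1 for the difference between days, 1616, 1594 and 2317 for control days 3, 6 and 9 against day 0, 854 for control day 9 against day 3 and 66 for irradiated day 9 against day 3. Array quality weights gave 1242 at day 3, 0 at day 6, 5610 at day 9, 1607 for the difference, 2683 for control day 6 against day 0, 6336 for control day 9 against day 3 and 3448 in the irradiated arm. Only the groups compared gave 569 at day 3, 0 at day 6 (limma; 2345 had an unadjusted p under 0.05 in the fit of all libraries, and limma-voom called 21), 0 for the difference, 2487 and 773 for control days 3 and 6 against day 0 and 739 in the irradiated arm. No filter gave 73 at day 6, 534 at day 9, 26 for the difference and 66 in the irradiated arm. For the difference, pseudocount 0.1 and quantile normalization gave 0 (2337 had an unadjusted p under 0.05 with pseudocount 1), and median-of-ratios scaling, the replicate block, limma-voom and nuclear rescaling 1 each. At day 6 the replicate block gave 13 and limma-voom 21, at day 9 quantile normalization 1246, and in the irradiated arm pseudocount 5 gave 263. The cause was not tested.

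With each replicate left out, the counts ranged from 571 (without control_day3 replicate 1) to 1697 (without irradiated_day6 replicate 3) averaged over days, 26 (control_day3 replicate 3) to 230 at day 3, 7 (control_day6 replicate 1 or irradiated_day6 replicate 1) to 985 (irradiated_day6 replicate 3) at day 6, 94 (irradiated_day9 replicate 3) to 909 at day 9, and 0 to 351 (irradiated_day6 replicate 3) for the difference. Between days they ranged from 3425 to 5641, 3641 to 5171 and 5238 to 6802 for control days 3, 6 and 9 against day 0, 299 to 2353 for control day 9 against day 3, and 13 to 98 in the irradiated arm. Where a group was left with 1 library, it is assumed to vary like the other groups. Alternatives planned for deposited counts were not run, since the table holds FPKM. On a transcript of 1 kb, 1 fragment is 0.0325 to 0.0393 FPKM, the smallest value above 0 that this depth allows.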

Other observations

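Chosen only after the result was seen were the gene ontology terms, the choice of the class I genes, and the tests of fewer Langerhans and dendritic cells and of scaling.

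Averaged over days, irradiated skin gained class I antigen presentation genes while class II genes fell. All 7 class I genes looked at rose, H2-K1 by 0.79, B2m by 0.84 and the peptide transporter gene Tap1 by 0.90 (genes chosen after their values were seen). In gene ontology, cellular response to interferon-beta held 29 of its 39 tested genes among those that rose (adjusted p 3.08e-28), chemokine-mediated signaling 11 of 36 (3.36e-05) and the classical complement pathway 8 of 21 (0.000206), with C3 up by 1.72 and C4b by 1.61. Among the chemokine genes Cxcl13 rose by 2.61 and Ccl7 by 2.35, and Ccl22 fell by 0.93. Terms of class II presentation held 8 of 23 genes among those that fell (0.000131). At day 9 the glycolytic process held 10 of 43 among those that rose (1.88e-05). The hypergeometric test takes genes as independent draws, so these p-values make no allowance for correlation between genes.

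Class II genes fell in irradiated skin, with a median of -1.95 over 6 genes by limma-voom, averaged over days. Ciita, the activator of class II transcription, stood at -1.14 by limma on log2(FPKM + 1) (SE 0.168, adjusted p 0.00183, 0.694 against 2.77 FPKM). That scale compresses changes near 1 FPKM, so the size of this change cannot be set beside those of limma-voom. The lower Ciita makes lower transcription of class II genes a candidate explanation. Whether irradiated skin held fewer Langerhans and dendritic cells stays open as well. Averaged over days, 7 markers of these cells outside class II had a limma-voom median of -0.886, which is 0.454 of the class II median. Flt3 stood at -3.13, at low values (0.143 against 1.14 FPKM), Ccr7 at -1.51 and Cd207 at -0.64 (limma-voom adjusted p 0.103). At day 3 Cd207 (0.68), Ccr7 (0.42) and Zbtb46 (0.07) stood above 0, none passing, and the other markers below 0. Fewer such cells cannot be told apart from lower transcription, because cells that carry these markers can also express Ciita and whole skin was sequenced.

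Fewer genes passed between days 3 and 9 in the irradiated arm (147) than in the control arm (2780), a gap whose size depended on the setting and on single libraries. Array quality weights gave 3448 and 6336, fits of only the groups compared 739 and 3103, and the control arm held 299 without control_day3 replicate 3. Such counts do not test whether the arms changed differently. That difference was part of the F test of the irradiation effect between days, which 2 of 15271 genes passed. Scaling by the deposited totals as the whole cause of the gap is argued against by median-of-ratios scaling, which gave 174 and 2786. Slower progress along the control course may explain the gap and stays open: on an axis from control day 3 (0) to control day 9 (1) over 1000 genes, the irradiated day-9 libraries averaged 0.509 ± 0.123 and held-out control day-9 libraries 0.91 ± 0.249 (exact permutation test, two-sided p 0.2; 3 against 3 cannot go below 0.1). The lowest held-out control library, at 0.628, lay beside the highest irradiated one, at 0.629.

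Other splits of the samples were counted for comparisons of at least 3 libraries per group. Averaged over days, 1 of 100 splits within days, the real one, gave as many genes (1058, highest other 30). Mixed splits leave any real difference between the arms in their spread, which lowers their counts. The libraries may also not be separate animals. The count was thus rare among these splits, which does not exclude chance as its source. At day 9 (822; highest other 1) and for irradiated day 9 against day 3 (147; highest other 1), the 10 splits of the 6 libraries, of which 1 was as large, are too few for a share under 0.05.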
